A study of Mus musculus with 6 samples.

How the data were processed

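Poly(A) RNA was sequenced from 6 cultures of primary mouse myoblasts, the mononuclear precursors of muscle fibres, after 24 h in differentiation medium with 2% horse serum. Per the labels' protocols, the cells were sorted from hindlimb muscle by alpha7-integrin and CD34, plated at 26000 cells per cm2, and 100 ng of RNA with an integrity number of 8 to 9.4 entered stranded library preparation, which gave libraries of 344 to 424 bp. The group and replicate number of each library were taken from its title: 3 libraries labelled Hdac11 knockout (KO) and 3 labelled wild type (WT). The series' design text calls them biological replicates from KO and WT mice.

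The submitters' processing notes name FastQC, Trimmomatic, TopHat2 2.0.8, Bowtie2, featureCounts and DESeq2 and the build GRCm38, with no order or settings; other settings are not given in the sources used here. The deposited table held 21778 gene symbols with raw counts per gene and library, which the authors did not normalize. Its normalized columns were a signal in which the authors had divided each raw count by 1 size factor per library, per the file headers and the values. The deposited log2 fold changes of KO over WT and their standard errors were the authors' own, as were the test score (the fold change divided by its error) and the p-values and adjusted p-values. Of the authors' adjusted p-values, 7268 were NA and were left so.

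The raw counts were used for all fits here. Genes were kept with edgeR's filterByExpr by genotype, which left 14835 genes and dropped 6943. The counts were scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests without covariates, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05, in R 4.3.3. Standard errors of log2 fold changes were derived from the F statistic. CPM values are counts relative to the TMM-scaled library size. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. Gene lists were tested with limma's camera on edgeR log-CPM values with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 5 tested genes. camera with an estimated correlation and fry were run beside it. A list score is the mean over a list's genes of log2 CPM centred on the 6 libraries.

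In total 33 lists of pathways, quality signs and cell type markers were fixed before the data were examined, as were the design, most alternatives and the rule for named genes. That rule takes the histone deacetylases, up to 12 genes per direction with the largest fold change among genes that pass with a mean of at least 5 CPM and no overlap of the groups, up to 4 members of each list with the smallest p and, for lists with no called member, up to 2 with the highest mean. Where fewer than 5 genes pass in a direction it takes the 5 with the smallest p. The genes printed are a subset of those the rule takes, picked after their values were seen. Cd34, Id3, Myod1, Myf5 and Dcn lie outside the rule.

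The scripts were tested on simulated counts for the KO against WT comparison, over 14835 genes with 200 genes changed. The 200 were drawn from genes outside the mitosis list with a mean of at least 5 CPM. At 2-fold and 4-fold, edgeR recovered 21% and 92% of changed genes with 14 false calls, DESeq2 64% and 96% with 68, and limma-voom 20% and 89% with 12. With no gene changed they made 1, 18 and 1 calls. A list changed 2-fold was recovered by all 3, and in that draw the unchanged sarcomere list was called too. In 20 further draws with edgeR fits and only the mitosis list changed, that list was recovered in 20 and other lists were called 1 time in all. The simulated genes were drawn independently, while the estimated inter-gene correlation in the data was 0.77 for the mitosis list and 0.66 for the sarcomere list. These draws therefore cannot show how often camera calls unchanged lists in the data.

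Totals ran from 16742457 to 22835394 counts per library. Alternatives covered the scaling, the low-count filter, the test, a replicate block, each library left out, the threshold, the set test and the authors' deposited calls; covariates for sex and further edgeR and DESeq2 settings were added after seeing the data. Coordinates of the deleted exon are from the labels (mm9) and were matched to the GENCODE vM1 annotation of that build. Gene positions around Hdac11 are from a RefSeq table of GRCm38, in which 82.8% of the symbols were found. No other build was mixed with these. Reads over single exons were not analysed here.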

Results

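The series compared the transcriptome of Hdac11 knockout and wild-type mouse myoblasts at day 1 of differentiation. HDAC11 is the class IV histone deacetylase. Each group held 3 libraries. Total counts were 20038283, 20287743 and 16742457 in KO replicates 1, 2 and 3 and 22835394, 19737409 and 19673388 in WT replicates 1, 2 and 3. Xist and Y-linked counts showed a male pattern in KO replicate 3 and WT replicate 1 and a female pattern in the others, so each group held 1 male and 2 female libraries. The first principal component held 47.5% of the variance. Correlations of log-CPM were 0.949 to 0.973 within groups and 0.905 to 0.973 between groups.

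Hdac11 itself was at 33.5 and 30.2 CPM in KO replicates 1 and 3, and at 76.4 CPM in the library labelled KO replicate 2. The WT libraries were at 63.0, 79.5 and 73.8 CPM. The KO mean was 46.7 ± 25.8 CPM (SD, n = 3) and the WT mean 72.1 ± 8.40 CPM (SD, n = 3), a log2 fold change of -0.63 (SE 0.35) with an edgeR adjusted p of 0.380. An exact two-sided permutation test of the 6 CPM values gave p = 0.3, where 3 against 3 cannot go below 0.1. The count in the library labelled KO replicate 2 was within the range of the WT libraries, unlike those of KO replicates 1 and 3. A gene-level count does not show whether the exon was deleted, and reads over single exons were not analysed here. This library enters every KO value given here unless it is said to be left out. Without it the edgeR log2 fold change was -1.18 (SE 0.18) with an adjusted p of 0.116, and DESeq2, in a setting chosen after seeing the data, gave an adjusted p of 3.67e-05. The library is picked out here by its Hdac11 count, so the larger difference and smaller error follow from that choice. They are no independent test of Hdac11. The highest adjusted p over the alternatives was 0.823, from DESeq2 without KO replicate 3, with a log2 fold change of -0.40.

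The allele lacks exon 3, at chromosome 6, 91109155 to 91109255 on mm9. In the annotated transcript of 2653 nt and 10 exons this coding exon spans 101 nt, or 3.81% of the length. Joining exon 2 to exon 4 in that sequence gave a reading frame of 59 amino acids with a stop in exon 4, the length and exon stated in the labels. The intact annotated frame was 347 amino acids, while the labels give 349. On GRCm38, Hdac11 lies on chromosome 6 from 91156670 to 91174692. Of the 18 tested genes within 1 Mb, 0 passed edgeR's adjusted threshold, 5 had an unadjusted p under 0.05, and 0 passed in the authors' deposited table. Because edgeR called 0 of all 14835 tested genes, its 0 near Hdac11 was fixed by that and says nothing about the region. Over all tested genes, 17.7% had an unadjusted p under 0.05 in edgeR. Whether the share near Hdac11 differs from this was not tested.

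Across the other histone deacetylases, Hdac9 had the largest absolute log2 fold change, -1.34, with 10.1 ± 4.99 CPM in KO and 25.5 ± 6.99 in WT (SD, n = 3). Hdac7 was at 46.4 ± 6.85 CPM in KO and 27.9 ± 4.08 in WT. Both are class IIa enzymes, and neither passed in edgeR over all genes (adjusted p = 0.193 and 0.158). The list of 11 genes had 0 members past the threshold adjusted over the list alone and 0 over all genes in edgeR, with 1 higher and 1 lower at an unadjusted p under 0.05 and 1 higher and 1 lower called by DESeq2. The log2 fold changes of Hdac1, Hdac2, Hdac3, Hdac8 and Hdac10 were 0.16, 0.09, 0.20, 0.22 and 0.41, and those of Hdac4, Hdac5 and Hdac6 were -0.33, -0.44 and -0.34. Without WT replicate 2 the value of Hdac1 was -0.0083, and without WT replicate 1 that of Hdac6 was 0.18.

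Gene lists of cell division had higher values in KO and gene lists of the contractile apparatus had lower values. Of 30 lists tested, camera with its preset correlation called 4 higher and 5 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.657 with an estimated correlation). Called on other splits of the 6 libraries into 3 and 3, camera gave up to 11 lists. fry called 1 list by direction and 5 in either direction. Over single genes, edgeR called 0 genes higher and 0 lower in KO, with a smallest adjusted p of 0.138. At an unadjusted p under 0.05 edgeR had 1465 genes higher and 1161 lower, 2626 in all, where chance gives 742. DESeq2 called 608 higher and 322 lower, limma-voom called 0 and 0 with 2550 genes at an unadjusted p under 0.05, and an edgeR exact test, chosen after seeing the data, called 496 genes higher in KO and 174 genes lower in KO. The authors' deposited table held 609 higher and 309 lower, of which 913 were shared with the DESeq2 calls. KO and WT values did not overlap for 23.4% of tested genes, where chance gives 10%. Without KO replicate 3 the number at an unadjusted p under 0.05 in edgeR was 1338, and without WT replicate 2 it was 1609. DESeq2 called 175 genes higher without KO replicate 3 and 326 without WT replicate 2. It called 558, 159 and 39 lower without KO replicates 1, 2 and 3, and 712, 44 and 207 lower without WT replicates 1, 2 and 3.

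The genes with the smallest p on the higher side were Foxm1, a transcription factor of the G2/M program, Ptprg, a receptor tyrosine phosphatase, Aspm, a spindle protein, Slc1a5, a glutamine transporter, and Fbln1, a matrix protein. Foxm1 was at 83.9 ± 17.8 CPM in KO and 29.0 ± 1.01 in WT (SD, n = 3), a log2 fold change of 1.53. Ptprg, Aspm, Slc1a5 and Fbln1 had log2 fold changes of 1.38, 1.39, 1.53 and 1.30. On the lower side stood Col4a5, a basement membrane collagen, Porcn, which acylates Wnt ligands, Mid1, Setbp1 and P2ry14. Porcn was at 20.6 ± 6.40 CPM in KO and 67.4 ± 16.8 in WT. Col4a5, Mid1 and Setbp1 had log2 fold changes of -1.41, -1.05 and -1.05, and P2ry14 was at 0.113 CPM in KO and 1.13 in WT. None of these 10 passed in edgeR (adjusted p = 0.138 for each), and in the authors' deposited table the adjusted p of P2ry14, the highest of the 10, was 0.00496.

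All 46 tested genes of mitosis and G2/M had a higher mean in KO, with a median log2 fold change of 1.41. In edgeR 46 were higher adjusted over the list alone and 0 over all genes, with 46 at an unadjusted p under 0.05 and 45 called by DESeq2. Ccnb2, a mitotic cyclin, was at 54.1 ± 7.25 CPM in KO and 20.9 ± 4.90 in WT, and Mki67 at 308.5 ± 61.3 and 123.3 ± 36.3 (SD, n = 3). Kif4, a chromosome-associated kinesin, Racgap1 and Top2a had log2 fold changes of 1.56, 1.28 and 1.41. The list passed camera (adjusted p = 2.23e-32) but not with an estimated correlation (adjusted p = 0.657 with an estimated correlation). Without the library labelled KO replicate 2 the number adjusted over the list alone was 46.

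DNA replication and G1/S genes showed the same direction, with 40 of 40 positive and a median log2 fold change of 1.23. In edgeR 37 were higher adjusted over the list alone and 0 over all genes, with 37 at an unadjusted p under 0.05 and 31 called by DESeq2. Mcm5, a subunit of the replicative helicase, was at 56.2 ± 27.3 CPM in KO and 16.4 ± 2.46 in WT (SD, n = 3). Pole, Pold1 and Dnmt1 had log2 fold changes of 1.54, 1.24 and 1.17. camera gave an adjusted p of 4.03e-19, and the adjusted p was 0.657 with an estimated correlation. Without the library labelled KO replicate 2 the number adjusted over the list alone was 39.

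Sarcomere proteins were lower in KO as a list, with 42 of 43 tested genes negative and a median log2 fold change of -1.45. Embryonic myosin heavy chain, Myh3, was at 6444 ± 4079 CPM in KO and 21322 ± 11439 in WT (SD, n = 3), and Ttn at 2280 ± 837 and 5403 ± 2461. Des was at 1025 ± 299 and 1886 ± 151 CPM, and Neb and Tnni1 had log2 fold changes of -1.51 and -1.69. In edgeR 0 genes were lower adjusted over the list alone (smallest p 0.0530) and 0 over all genes, with 27 at an unadjusted p under 0.05. DESeq2 called 20 over all genes and 33 adjusted over the list alone, and limma-voom 27 adjusted over the list alone. camera gave an adjusted p of 4.86e-14, and the adjusted p was 0.657 with an estimated correlation. The list scores overlapped, at 0.15 in KO replicate 1 and -0.05 in WT replicate 1. Without either of these libraries 37 and 35 genes were lower adjusted over the list alone.

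Calcium handling and excitation-contraction coupling followed, with 23 of 24 genes negative and a median log2 fold change of -1.36. In edgeR 15 were lower adjusted over the list alone and 0 over all genes, with 17 at an unadjusted p under 0.05 and 11 called by DESeq2. Ryr1, the calcium release channel of the sarcoplasmic reticulum, was at 754 ± 216 CPM in KO and 2049 ± 789 in WT (SD, n = 3), and Trdn at 46.7 ± 37.1 and 192.2 ± 61.1. The camera adjusted p was 3.16e-10, and it was 0.657 with an estimated correlation. Leaving out the library labelled KO replicate 2, KO replicate 3, WT replicate 2 or WT replicate 3 left 0 genes adjusted over the list alone. Neuromuscular junction genes had a median log2 fold change of -0.57 with 13 of 15 negative (camera adjusted p = 0.000512), and the adjusted p was 0.657 with an estimated correlation. Oxidative phosphorylation genes had a median of -0.16 with 37 of 40 negative (camera adjusted p = 0.00118), and the adjusted p was again 0.657 with an estimated correlation. Without WT replicate 1 the camera adjusted p of oxidative phosphorylation was 0.0762. In both lists edgeR had 0 genes adjusted over the list alone and 0 over all genes, with 8 and 4 lower and 1 and 0 higher at an unadjusted p under 0.05 and 2 and 1 called lower by DESeq2.

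**Figure D1:**
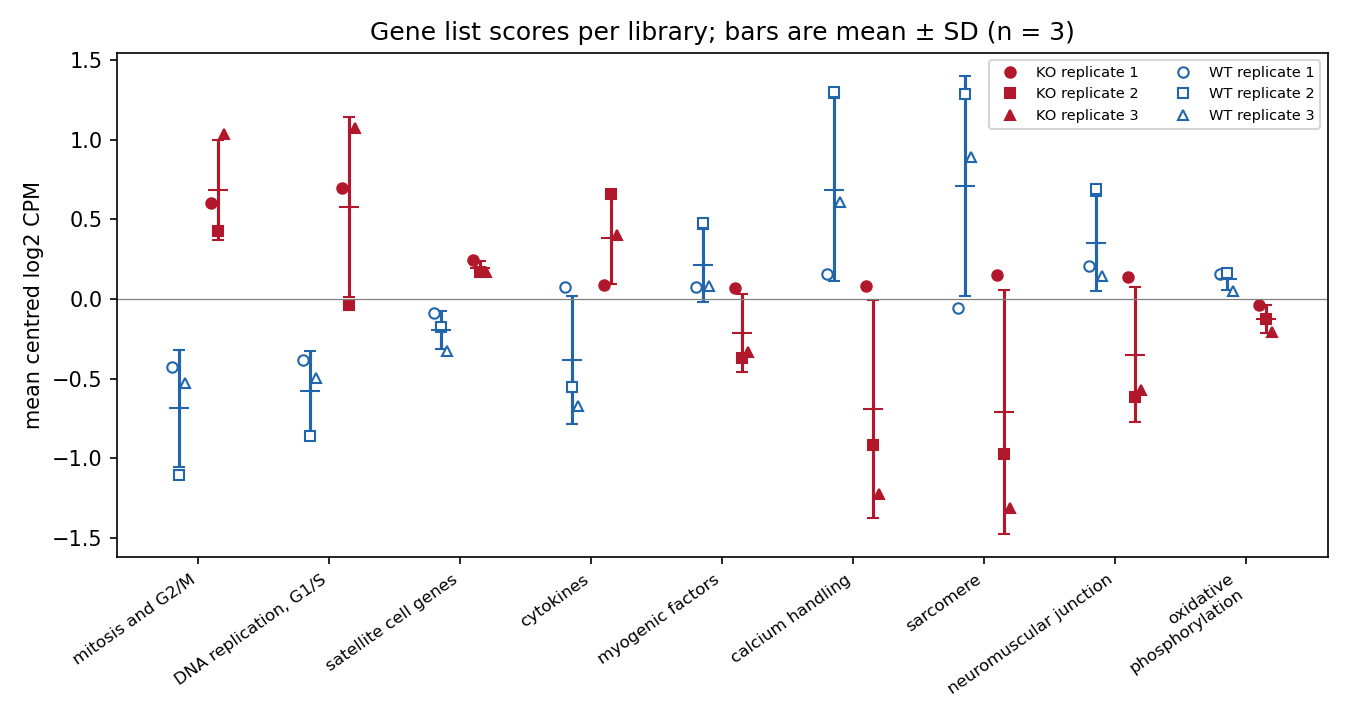
Mean centred log2 CPM of 9 gene lists in each library, with filled red symbols for KO and open blue symbols for WT, bars showing mean ± SD (n = 3). The mitosis scores run from 0.43 to 1.03 in KO and from -1.11 to -0.43 in WT, while the sarcomere scores of KO replicate 1 and WT replicate 1 are 0.15 and -0.05.

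Satellite cell and progenitor genes had a median log2 fold change of 0.39 with 16 of 24 positive. In edgeR 5 were higher adjusted over the list alone and 0 over all genes, with 6 higher and 1 lower at an unadjusted p under 0.05 and 5 called higher by DESeq2. These were Met, the hepatocyte growth factor receptor, Fgfr4, Hes1, a Notch target, Vcam1 and Cd34, the last named after its value was seen. Met was at 159.3 ± 12.5 CPM in KO and 93.8 ± 10.5 in WT, and Cd34, a sorting antigen of these cells, at 10.7 ± 7.26 and 1.64 ± 0.996 (SD, n = 3). Itga7, which encodes the other sorting antigen, was at 1271 ± 124 CPM in KO and 1793 ± 274 in WT. The list of quiescence and progenitor genes of satellite cells missed the camera threshold (adjusted p = 0.0537, or 0.0177 without KO replicate 3) and passed fry (adjusted p = 0.0246). With all libraries its adjusted p was 0.657 with an estimated correlation. The number adjusted over the list alone was 1 without KO replicate 3, 0 without WT replicate 3 and 9 without WT replicate 1.

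Myogenic transcription factors and cofactors also missed the camera threshold (adjusted p = 0.0513), with 12 of 19 genes negative and a median log2 fold change of -0.31. The camera adjusted p of myogenic transcription factors and cofactors was 0.0146 without KO replicate 1, 0.0335 without KO replicate 3 and 0.0357 without WT replicate 3. With all libraries its adjusted p was also 0.657 with an estimated correlation. Myog, which drives terminal differentiation, was at 1458 ± 430 CPM in KO and 2178 ± 288 in WT (SD, n = 3), and Mef2d at 272.5 ± 53.7 and 440.3 ± 75.5. Neither was called by DESeq2 (adjusted p = 0.216 and 0.0627). In edgeR 0 passed adjusted over the list alone and 0 over all genes, with 1 higher and 6 lower at an unadjusted p under 0.05. DESeq2 called Eya2 higher, at 2.77 ± 2.25 CPM in KO and 0.504 ± 0.0336 in WT, and Myf6 and Lmod3 lower, with edgeR log2 fold changes of -3.57 and -1.50. Lmod3, a member of the list as fixed, encodes a thin filament protein of the sarcomere and not a transcription factor. Eya2 was at 0.537 CPM in KO replicate 2, near the 0.529 of WT replicate 3. Myf6 overlapped between the groups, at 3.14 CPM in KO replicate 1 and 2.75 in WT replicate 3, while Lmod3 did not. The authors' deposited adjusted p of Myf6 was 0.0611. Myod1 and Myf5, determination factors named after their values were seen, had log2 fold changes of -0.05 and -0.02, and of 0.10 and 0.17 with scaling by library totals only. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was at 1069 ± 185 CPM in KO and 1669 ± 203 in WT with an edgeR adjusted p of 0.210.

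The list of cytokines and chemokines had a median log2 fold change of 0.74 with 13 of 17 positive (camera adjusted p = 0.0385), and the adjusted p was 0.657 with an estimated correlation. Ptgs2, Cxcl12 and Csf1 were higher adjusted over the list alone in edgeR, and 0 genes passed over all genes. At an unadjusted p under 0.05 edgeR had 4 higher and 1 lower. The lower one, Tnfaip3, had an adjusted p of 0.182 in the authors' deposited table. DESeq2, counted over all list members including those the filter dropped, called 3 higher and 1 lower. The authors' deposited table held 3 higher and 0 lower. Cxcl12 was at 129.0 ± 46.3 CPM in KO and 24.3 ± 17.1 in WT (SD, n = 3). Without the library labelled KO replicate 2 the camera adjusted p of cytokines and chemokines was 0.372, and without WT replicate 3 it was 0.0773. The p53 target list had a median of 0.35 (camera adjusted p = 0.0385), and the adjusted p was 0.806 with an estimated correlation. Its member that was higher adjusted over the list alone was Gtse1, a microtubule-associated protein of G2/M, and Cdkn1a is a member with a negative value. In edgeR 0 of the p53 targets passed over all genes, with 9 higher and 2 lower at an unadjusted p under 0.05 and 1 called higher by DESeq2. The camera adjusted p of p53 target genes was 0.0907 without the library labelled KO replicate 2, 0.0731 without KO replicate 3 and 0.269 without WT replicate 1. The type I interferon list had a median of -0.41 with 23 of 30 negative (camera adjusted p = 0.0465), and the adjusted p was 0.860 with an estimated correlation. In edgeR 0 of its genes passed adjusted over the list alone and 0 over all genes, with 1 higher and 2 lower at an unadjusted p under 0.05 and 0 called by DESeq2. The camera adjusted p of type I interferon response was 0.0630, 0.643, 0.173 and 0.105 without KO replicate 1, KO replicate 3, WT replicate 1 and WT replicate 3.

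**Figure D2:**
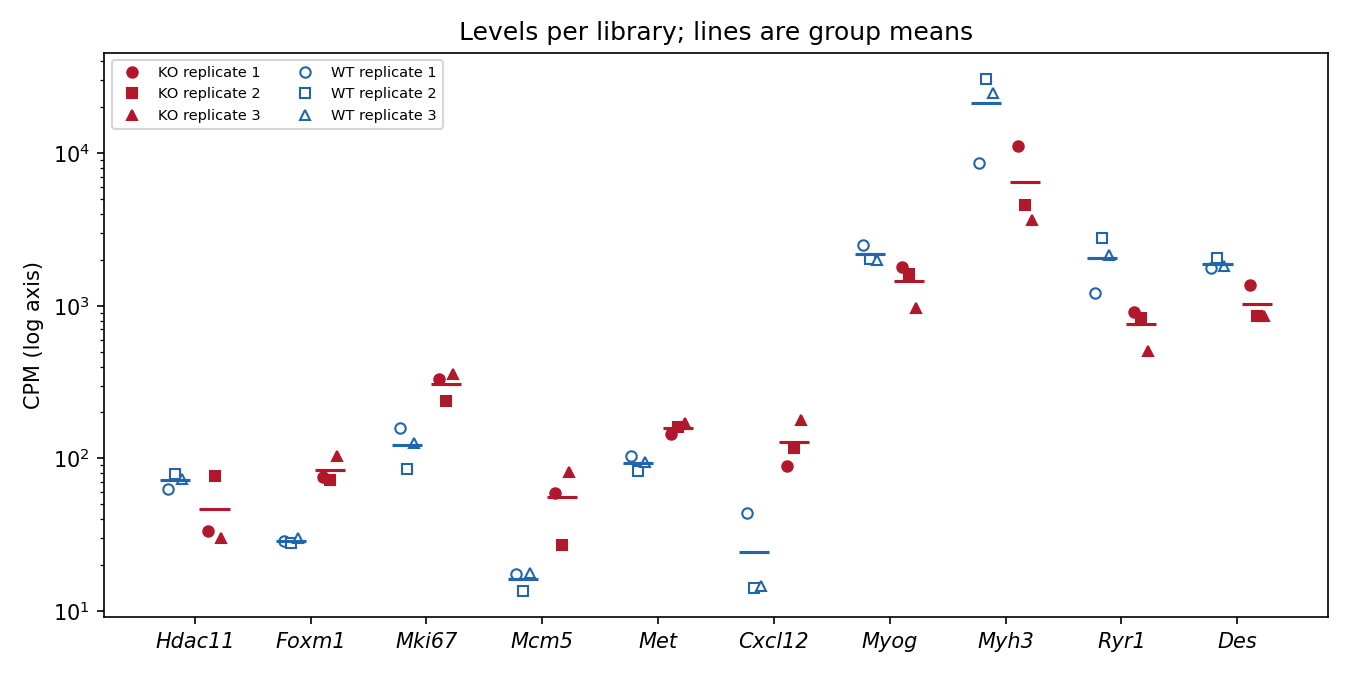
CPM of 10 genes in each library on a log axis, with filled red symbols for KO, open blue symbols for WT and lines at the group means (n = 3). Hdac11 in the library labelled KO replicate 2 lies at 76.4 CPM, beside the WT libraries at 63.0 to 79.5 CPM.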

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

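The settings with sex covariates, the edgeR exact test and further edgeR and DESeq2 options were chosen after seeing the data; the others were fixed earlier. No setting varied the depth, so its part in the count of 0 genes in edgeR was not tested. In counts simulated at this depth edgeR recovered 21% of 2-fold and 92% of 4-fold changes. The changed genes there had a mean of at least 5 CPM, so genes below that level are not covered. Each result was compared once per setting, so the counts that follow are pairs of a result and a setting, not distinct genes or lists. Of the pairs for main results, 185 stayed within their bounds and 40 moved. For the single genes chosen for the text, 1662 pairs kept their side of the threshold, 197 passed it and 12 changed sign. For single lists, 466 pairs kept their side, 26 passed the threshold, 44 no longer passed and 31 changed direction. None of the lists that changed direction was called in the first place. Scaling by library totals shifted the median log2 fold change of all genes to 0.14. The cause of the differences below was not tested.

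The numbers of genes higher in KO and genes lower in KO were 0 and 0 in edgeR, 608 and 322 with DESeq2, 496 and 174 with the edgeR exact test, 862 and 691 when DESeq2 had a sex covariate, and 609 and 309 in the authors' deposited table. DESeq2 genes higher in KO ran from 175 to 810 and DESeq2 genes lower in KO from 39 to 712 leaving out 1 library. edgeR genes with unadjusted p under 0.05 ran from 1338 to 3133. Gene lists past the threshold were 9 with camera, 0 with an estimated correlation, 1 with fry and 5 with fry mixed, and 6 to 10 leaving out 1 library.

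For sarcomere proteins, genes adjusted over the list alone were 21 with upper-quartile factors, 20 with library totals only, 26 with no filter, 33 with DESeq2, 27 with limma-voom, 35 with the edgeR exact test, 35 in edgeR with a sex covariate and 35 in DESeq2 with one. Leaving out 1 library gave 0 to 37 for sarcomere proteins, 0 to 22 for calcium handling and excitation-contraction coupling and 0 to 9 for satellite cell genes. Pairing of libraries by replicate number was not seen in their deviations from the group means. In these deviations same-numbered libraries had r of -0.25, -0.07 and 0.05. By them 0 of 6 libraries correlated best, among those of the other group, with their own number. With so few libraries per group this cannot exclude a shared batch. By log-CPM itself, WT replicate 1 correlated best with KO replicate 1 (r = 0.973). With a replicate block, genes adjusted over the list alone in calcium handling and excitation-contraction coupling were 7, and lists past the threshold were 11. The log2 fold change of Hdac1 ran from -0.0083 to 0.32 and that of Hdac6 from -0.54 to 0.18 leaving out 1 library. That of Myod1 was 0.10 with library totals only and ran from -0.17 to 0.13 leaving out 1 library. That of Myf5 was 0.17 with library totals only, 0.0011 with no filter, 0.045 with limma-voom and 0.028 with the replicate block, and ran from -0.24 to 0.31 leaving out 1 library.

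Lists not called that changed direction had these camera adjusted p values. With library totals only it was 0.952 for immediate early and heat shock genes, limb and axial position genes and endothelial markers. It was 0.988 for glycolysis and hypoxia response with no filter, and 0.983 for TGF-beta and BMP response and 0.761 for limb and axial position genes with a mean CPM of at least 5. With DESeq2 it was 0.962 for mitochondrially encoded genes and limb and axial position genes, and 0.974 for mitochondrially encoded genes when DESeq2 had a sex covariate. With the replicate block it was 0.983 for cyclin-dependent kinase inhibitors and pocket proteins. Leaving out 1 library it ran from 0.798 to 0.999 for class I, II and IV histone deacetylases, 0.155 to 0.985 for myoblast fusion and adhesion, 0.782 to 0.999 for cyclin-dependent kinase inhibitors and pocket proteins, 0.516 to 0.999 for TGF-beta and BMP response, 0.483 to 0.967 for glycolysis and hypoxia response, and 0.123 to 0.959 for extracellular matrix proteins and remodelling enzymes. It ran from 0.392 to 0.992 for immediate early and heat shock genes, 0.371 to 0.994 for unfolded protein and integrated stress response, 0.00364 (without WT replicate 3, where the list passed) to 0.967 for mitochondrially encoded genes, 0.419 to 0.952 for limb and axial position genes and 0.706 to 0.994 for endothelial markers.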

Other observations

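Of the tests below, those of scaling, fibroblast genes and the deleted exon were chosen after the result was seen, as was the demand that a value pass its bound by more than its spread. Lists that camera did not call held single genes that differed. In the fusion and adhesion list Ehd2 and Kirrel were higher and Elmo1 lower adjusted over the list alone, with log2 fold changes of 1.39, 0.99 and -1.52 and 0 over all genes in edgeR, where 4 members were higher and 4 lower at an unadjusted p under 0.05 and DESeq2 called 2 higher and 3 lower. Ebp was lower in the cholesterol list adjusted over the list alone, with a log2 fold change of -0.97, and Rbl1, a pocket protein, was higher in its list with 1.08. The Notch list had Hes1 alone past the threshold adjusted over the list alone, and Lfng had a value of 1.04. In the TGF-beta and BMP list 0 genes passed adjusted over the list alone in edgeR, with 3 higher and 4 lower at an unadjusted p under 0.05. Bambi, the member with the smallest p, had a log2 fold change of 1.56 and Id3, named after its value was seen, 1.13. Neither was called by DESeq2, and the authors' deposited table gave Bambi an adjusted p of 0.0495. Tgfb3, Tgfb2 and Fst, the 3 called lower by DESeq2, had -1.40, -1.64 and -1.47.

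The camera adjusted p was 0.931 for the histone deacetylases, 0.931 for cyclin-dependent kinase inhibitors, 0.581 for fusion genes, 0.285 for Notch, 0.765 for TGF-beta, 0.186 for fatty acid oxidation, 0.765 for glycolysis, 0.108 for cholesterol, 0.565 for interleukin-10 signalling and 0.765 for extracellular matrix. The list of cholesterol biosynthesis had 0.00288 without KO replicate 3, and fatty acid oxidation and lipid handling 0.0426 without WT replicate 3. With all libraries the adjusted p of both was 0.860 with an estimated correlation. With all libraries it was 0.865 for immediate early and heat shock genes, 0.765 for the unfolded protein response, 0.865 for mitochondrially encoded genes (0.00364 without WT replicate 3, and with all libraries an adjusted p of 0.934 with an estimated correlation) and 0.858 for limb position genes. For markers of other cells it was 0.640 for fibroblasts, 0.765 for leukocytes, 0.865 for endothelium, 0.204 for pericytes and smooth muscle and 0.706 for Schwann cells and glia. Mbp, a myelin protein gene, was higher adjusted over the list alone among the Schwann and glial markers, with a log2 fold change of 1.35 and an edgeR adjusted p of 0.163 over all genes. The replication-dependent histone, adipocyte and sex-linked lists had 4, 4 and 1 tested genes and were not tested as lists. Of the histone genes, Hist1h2be and Hist1h2bc were lower adjusted over the list alone, with values of -1.53 and -1.10. Histone genes share near-identical copies and their counts are uncertain. Poly(A) RNA was sequenced, while mRNAs of replication-dependent histone genes mostly lack a poly(A) tail. These values are therefore no measure of histone expression in dividing cells. The median, mean and test direction differed in sign in 8 lists, the extracellular matrix list among them with a median of -0.28. In that list 9 genes were higher and 1 lower at an unadjusted p under 0.05 in edgeR, 0 passed adjusted over the list alone, and DESeq2 called 3 higher and 0 lower.

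The higher cell cycle lists and lower muscle lists may have a technical source. A difference in scaling moves all lists of a library alike, and is argued against as the whole cause by the mitosis score minus the sarcomere score, which was 2.80 higher in KO (SE 0.800) with no overlap between the groups. Fibroblasts mixed into the KO cultures are argued against by Dcn and Pdgfra, which reached at most 0.677 CPM in a KO library, though the sort would also remove such cells; 9 of the 20 fibroblast markers were tested. Libraries that had differentiated less stay open. The KO coefficient of the mitosis score was 0.956 (SE 0.389) with the sarcomere score in the model and 1.37 without it. It was past the bound set beforehand of 0.687 by less than its error. The model takes out a difference in the sarcomere score whatever its source. It therefore cannot tell less differentiation through the genotype from less differentiation for other reasons. The genotype itself is the biological difference the design names, and it stays open too, as untested.

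Hdac11 at the wild-type level in the library labelled KO replicate 2 could come from a wild-type library under a knockout label. On an axis from the WT mean at 0 to the KO mean at 1, that library, left out of the means, lay at 0.661, past the bound set beforehand but above WT replicate 1 (0.617) by less than the SD of the WT positions (0.349), so a wrong label cannot be told apart from a right one. KO replicates 1 and 3 lay at 0.542 and 1.19, and WT replicates 2 and 3 at -0.075 and 0.344. A gene-level count that does not see the deleted exon, 3.81% of the annotated transcript, is argued against as the whole cause: KO replicates 1 and 3, labelled with the same allele, were at 46.4% and 41.8% of the WT mean, where the WT libraries ran from 87.4% to 110.3%.

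Over the 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. edgeR's count of 0 was met in 10 of 10 splits, with a highest other count of 0. Any count is at least 0, so the 10 of 10 was fixed in advance and decides nothing. For genes at an unadjusted p under 0.05 the real split had 2626 and the highest other 1232, and for DESeq2 calls 930 and 238, so that 1 split, the real one, was as large in each. For gene lists past the threshold in camera the real split had 9 and the highest other 11, and 5 of the 10 splits had 9 or more.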
